A study of Mus musculus with 16 samples.

How the data were processed

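RNA was measured in 16 libraries of sorted dorsal root ganglion cells, 4 in each combination of genotype label (fl/fl or CKO) and treatment (PTX or vehicle). Per the labels, retrogradely traced cells that took up fluorescent wheat germ agglutinin were sorted by flow cytometry and about 500 ng of RNA entered a stranded poly(A) library preparation. Libraries were read as 50-base single ends. Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned to mm9 with TopHat2, and reads were counted per gene with HTSeq, none with a stated version. The deposited values are the authors' raw counts per gene, without normalization. Each of the 16 files held 22609 gene entries and 5 HTSeq summary lines, the values were whole numbers, and no columns of other series were used. Gene symbols are those of the files. Of these, 20043 are also current in the RefSeq table at hand, which belongs to another assembly and was used for names only, and 14 list members were matched through an older symbol.

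Counts assigned to genes ranged from 7906504 to 11668007 per library and genes with a count from 12136 to 15418. Of all counted alignments, 32.88 to 43.48 percent were assigned to genes, 13.73 to 25.39 percent fell on no annotated feature, 0.26 to 0.42 percent were ambiguous and 39.54 to 44.18 percent were not unique. No 2 libraries of a group were identical, and the lowest chi-square per degree of freedom among 24 pairs was 20.3, so the spread within groups was above counting error.

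Genes were filtered with filterByExpr, which left 14200, scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood F test, robust, all 16 libraries in 1 model, 12 residual degrees of freedom) in R 4.3.3. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes within a comparison and a threshold of 0.05. The common biological coefficient of variation was 0.939. The comparisons were PTX against vehicle in each genotype label, CKO against fl/fl in each treatment, and their interaction. Ltbr and Scn10a were also compared by exact permutation of the log CPM over 70 assignments with a pseudocount of 1. Standard errors were derived from the fold change and its test statistic. For a gene with 0 counts in a group the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts a ratio of counts with its counting interval is given.

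Fixed lists, 19 of pathways or gene classes and 15 of cell type markers, were written before the data were examined, as were the comparisons, the rule for named genes and the alternatives except those marked below. Each list was tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01 and, beside it, with an estimated correlation. Counts of members called over all genes and of members called when adjusted over the list alone are given. The share of counts of a marker list is the sum of its members over all gene counts of a library, compared between groups by exact permutation of its mean log CPM.

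The named genes were Ltbr and Scn10a, then up to 10 genes in each direction with the largest fold among those past the threshold, with a mean of at least 5 CPM in the higher group, groups that did not overlap, and a symbol other than a clone or predicted-gene number. Where none passed in a direction, the 3 with the smallest p under the same limits are given as values. For each list up to 4 called members with the smallest adjusted p follow, or the 2 most abundant members where none was called. The text gives part of the last set, and some genes that the rule names are not reported here.

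The alternatives were RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 4 libraries, a block for replicate number or for title date, each title date alone, the compared groups alone, the mean of glial and Schwann cell markers as a covariate, limma-voom with quality weights, DESeq2 1.42.0, and leaving out each library in turn. Chosen after seeing the data were the analysis without the 4 libraries of the earlier PTX date, the covariate of neutrophil markers and that of sensory neuron markers. The neuron marker mean did not overlap between treatments (8.64 to 9.56 after PTX and 5.21 to 8.00 after vehicle in fl/fl, 8.12 to 9.58 and 4.95 to 7.16 in CKO). Nor did the Schwann cell mean, a part of the glial covariate. Both covariates therefore take up much of the treatment difference, and a PTX call lost with them does not show composition as its cause. Replicate numbers were checked for pairing by correlating the deviations of libraries with the same number. In the genotype comparison under PTX the correlations were 0.37, 0.40, 0.39 and 0.22, and 6 of 8 libraries matched their own number best, and a replicate block changed no call there.

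The analysis was tested on simulated data with 200 changed genes of at least 5 CPM and the depth and dispersion of these libraries. A 2-fold change was recovered for 0 percent in all 4 comparisons of 2 groups. A 4-fold change was recovered for 14 (PTX in fl/fl), 13 (PTX in CKO), 14 (genotype under PTX) and 13.5 percent (genotype under vehicle). A 16-fold change gave 68, 67, 62.5 and 65.5 percent. Camera called the 1 list planted at 2-fold and no other of 34, which does not test its calls in correlated lists. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Reads and exon-level counts were not analysed here.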

Results

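Gene expression was measured by RNA sequencing in tracer-labelled cells sorted from the lumbar dorsal root ganglia of male mice aged 8 to 16 weeks. These ganglia hold the cell bodies of the sensory neurons that serve the hind limb, wrapped by satellite glial cells. The mice carried floxed alleles of Ltbr, the gene of the lymphotoxin-beta receptor, an activator of NF-kB signalling. They had the floxed alleles alone (fl/fl) or together with a Cre recombinase under control of Nav1.8, the nociceptor sodium channel encoded by Scn10a (CKO). Each genotype had received vehicle or paclitaxel (PTX), a chemotherapy drug that stabilises microtubules and can cause painful neuropathy. The PTX dose was 6 mg per kg, given 3 times at intervals of 2 days. The treatment text attached to every library, vehicle included, describes PTX, and the libraries called vehicle here are those whose treatment label is water and whose titles do not name PTX. These labels were followed, so every comparison of PTX with vehicle rests on them. The fluorescent tracer, wheat germ agglutinin, entered the paw 16 days after the last injection, and ganglia were taken at 18 days. The labels place 4 libraries in each of the 4 groups, 16 in all, while the design text states 3 per group. The labels do not say that the libraries of a group came from separate animals. The p-values of single genes and of the exact tests between groups therefore measure the spread between these libraries, which may be technical. Those of the gene list test at the preset correlation rest on the spread between genes instead.

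Libraries held 7906504 to 11668007 gene counts and 12136 to 15418 genes with a count. The library titles carry dates. The PTX libraries share an earlier and a later September date, and the vehicle libraries an earlier and a later October date, with 2 libraries of each genotype on each. The labels do not say whether these dates mark tissue collection or library preparation. Date and treatment therefore cannot be separated, whereas genotype is balanced over dates. Levels are given as CPM, counts scaled to the effective size of each library, as mean ± SD over 4 libraries, and log2 fold changes with their standard error. An "edgeR adjusted p" is the p-value of edgeR's quasi-likelihood test, two-sided and adjusted by Benjamini-Hochberg over all 14200 genes tested. A "camera adjusted p" is that of limma's competitive gene list test, adjusted over 34 lists. Intervals on ratios of counts and lower bounds on folds cover counting error only.

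The targeted gene Ltbr was not lower in the libraries labelled CKO. In the PTX libraries labelled fl/fl it stood at 6.06, 8.61, 12.2 and 15.6 CPM, and in the PTX libraries labelled CKO at 23.3, 5.88, 19.5 and 28.4 CPM. The vehicle libraries gave 42.4, 51.4, 48.3 and 46.8 CPM under the fl/fl label, and 99.0, 54.3, 33.1 and 32.3 CPM under the CKO label. The difference by genotype label passed no exact two-sided permutation test, with p = 0.257 among the PTX libraries (log2 difference 0.69) and p = 0.914 among the vehicle libraries (0.06), where the smallest p that 4 against 4 libraries can give is 0.0286. The edgeR log2 fold changes of Ltbr were 0.86 ± 0.51 and 0.21 ± 0.50, each with an edgeR adjusted p of 1. Without replicate 1 of the vehicle CKO group the vehicle value turned to -0.24. Within dates, Ltbr was higher in both libraries labelled CKO than in both labelled fl/fl on the later PTX date and the earlier vehicle date, and lower in both on the later vehicle date. The mean on the earlier PTX date was 14.6 CPM under the CKO label and 7.34 CPM under the fl/fl label, with overlapping values. The counts cover the whole gene and the labels do not name the floxed exons, so reads from the remaining exons could hide a deletion. The genotype names below are those of the labels.

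**Figure D1:**
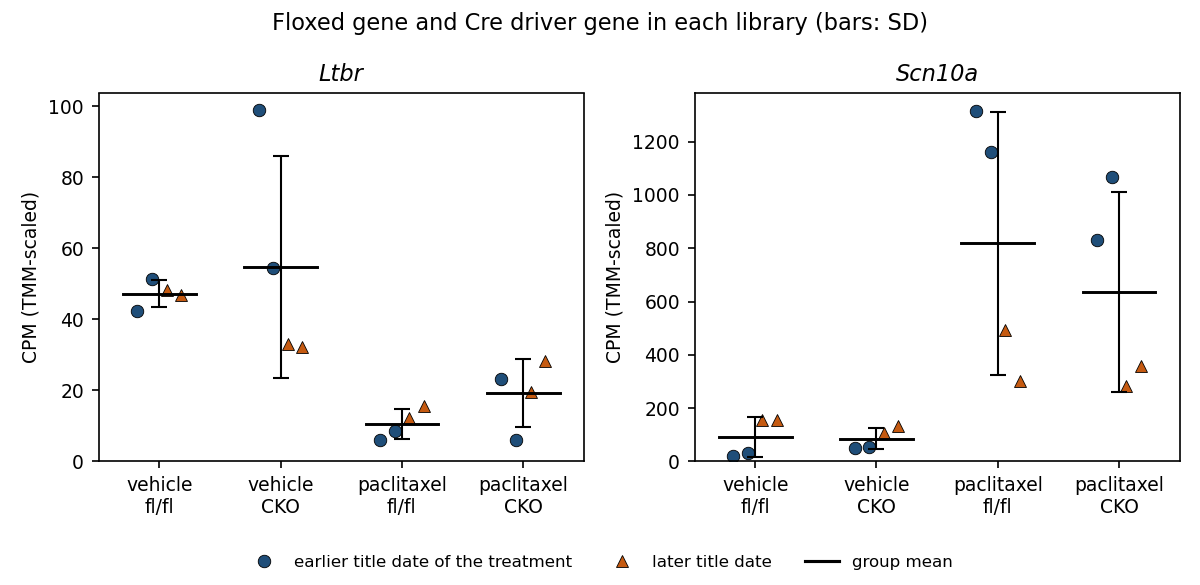
Ltbr and Scn10a in each of the 16 libraries, in CPM, by treatment and genotype label, where points are libraries, horizontal lines are group means and error bars are SD. Ltbr averages 10.6 and 19.3 CPM in the PTX libraries labelled fl/fl and CKO and 47.2 and 54.7 CPM in the vehicle libraries, and Scn10a averages 818 and 635 CPM against 90.8 and 85.4 CPM.

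Scn10a was higher and Ltbr lower after PTX than after vehicle with no overlap between libraries in either genotype label, and each of these 4 comparisons gave an exact permutation p = 0.0286, the smallest possible. Scn10a averaged 818 ± 495 CPM in PTX fl/fl, 635 ± 376 CPM in PTX CKO, 90.8 ± 74.8 CPM in vehicle fl/fl and 85.4 ± 39.7 CPM in vehicle CKO. It rose with PTX by 3.17 ± 0.70 on the log2 scale in fl/fl (edgeR adjusted p = 0.017) and by 2.89 ± 0.69 in CKO (edgeR adjusted p = 0.035). Ltbr fell by 2.15 ± 0.52 in fl/fl (edgeR adjusted p = 0.027), and its log2 difference of -1.50 ± 0.51 in CKO did not pass in edgeR (edgeR adjusted p = 0.12) but did in DESeq2 and limma-voom (adjusted p = 0.0219 and 0.0265). The fl/fl call of Ltbr was lost in 11 of 20 alternatives, with adjusted p-values from 0.00014 to 1.00 and log2 fold changes from -2.57 to -0.0045, the last with the glial covariate. Of the single libraries, it was lost without replicate 1, 2 or 3 of PTX fl/fl (edgeR adjusted p = 0.107, 0.0966 and 0.0513) or of vehicle fl/fl (0.0608, 0.0668 and 0.0525), and it was also lost without the earlier PTX date (0.319). The Scn10a call was lost in 9 of 20 alternatives in fl/fl (log2 1.11 to 3.88, adjusted p 0.00011 to 1.00) and 10 of 20 in CKO (0.45 to 3.18, 0.0014 to 1.00), with the lowest values under the neuron covariate. In fl/fl the single libraries were replicates 1 and 2 of PTX fl/fl (edgeR adjusted p = 0.0613 and 0.0557) and replicate 2 of vehicle fl/fl (0.0521). In CKO they were replicates 1 and 2 of PTX CKO (0.0877 and 0.125) and replicates 1, 2 and 3 of vehicle CKO (0.0850, 0.123 and 0.0824). By genotype label, the edgeR log2 difference of Scn10a was -0.36 ± 0.64 under PTX and -0.09 ± 0.64 under vehicle, and neither passed. The exact permutation test, on the mean of log2 CPM, gave -0.33 (p = 0.571) and 0.30 (p = 0.714), so the 2 measures differ in sign under vehicle. The vehicle value of Scn10a turned positive without replicate 3 or 4 of vehicle fl/fl (0.29 and 0.31) or replicate 1 or 2 of vehicle CKO (0.091 and 0.071).

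The first comparison asked what PTX changed in fl/fl mice. The genes called higher after PTX included genes of sensory neurons, and those called lower included genes of glia, Schwann cells, macrophages and connective tissue. Avil, the actin-binding protein advillin of peripheral sensory neurons, stood at 862 ± 355 CPM after PTX and 108 ± 67.1 CPM after vehicle, a rise of 2.99 ± 0.54 on the log2 scale (edgeR adjusted p = 0.0078). Trpv1, the heat and capsaicin channel of nociceptors, rose by 2.79 ± 0.58, from 56.7 ± 52.8 to 394 ± 47.6 CPM (edgeR adjusted p = 0.013). Mbp, the myelin basic protein, fell by 2.45 ± 0.33, from 2351 ± 371 to 431 ± 170 CPM (edgeR adjusted p = 0.0022). Lum, an extracellular matrix proteoglycan of fibroblasts, fell by 4.71 ± 0.60 (edgeR adjusted p = 0.0018). In all, 704 of 14200 genes passed at an edgeR adjusted p under 0.05, 454 higher and 250 lower after PTX, and 690 of them by more than 2-fold. The values of the 2 groups did not overlap for 2674 genes, 18.8 percent, where chance gives 2.86 percent.

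The marker lists are given with the shares of counts they took. Over 60 exact permutation tests on the mean log2 CPM of marker lists, the smallest Benjamini-Hochberg adjusted p was 0.122, so none passed adjustment. Of 16 tested pan-neuronal markers, 11 rose and none fell, or 13 and none when adjusted over the list alone, among them Avil, Stmn2 (2.25 ± 0.46), Prph (2.53 ± 0.52) and Scn9a (2.64 ± 0.59), which encode a microtubule regulator, the intermediate filament peripherin and the sodium channel Nav1.7. The camera adjusted p was 3.17e-13, with an adjusted p = 0.121 with an estimated correlation. The list took 1.70 ± 0.571 percent of counts after PTX and 0.392 ± 0.291 percent after vehicle. Peptidergic nociceptor markers behaved alike, with 6 of 14 up and 11 up adjusted over the list alone (camera adjusted p = 1.35e-10, and an adjusted p = 0.050 with an estimated correlation). They included Calca, the precursor of the neuropeptide CGRP (2.36 ± 0.50), Trpv1 and Adcyap1, the precursor of the neuropeptide PACAP (2.59 ± 0.42). Among 17 markers of non-peptidergic nociceptors 2 rose, 8 adjusted over the list alone, with Ret, the GDNF family co-receptor, up by 3.01 ± 0.53. The list rose with a median of 2.98 (camera adjusted p = 6.08e-07, and an adjusted p = 0.143 with an estimated correlation). That call was lost with the neuron covariate, where the median turned to -0.68 (camera adjusted p = 0.986), and with the glial covariate (0.75, camera adjusted p = 0.613). Of 14 pruriceptor markers, genes of itch-sensing neurons, 3 rose and 4 adjusted over the list alone (median 4.196, camera adjusted p = 8.5e-05, and an adjusted p = 0.121 with an estimated correlation). They included Sst, the somatostatin precursor, at 6.15 ± 3.29 CPM after PTX and 0 counts after vehicle, at least 85.9-fold higher. No marker of C low-threshold mechanoreceptors and cold-sensing neurons passed, and 5 of 11 rose adjusted over the list alone (median 1.61, camera adjusted p = 0.00034, and an adjusted p = 0.121 with an estimated correlation). The 24 markers of myelinated mechanoreceptors and proprioceptors held 2 that fell, the neurotrophin receptor gene Ntrk2 (-1.81 ± 0.37) and the axonal potassium channel gene Kcna1, and the same number adjusted over the list alone. The calls of the pruriceptor and C low-threshold lists were lost with the glial covariate (medians 3.76 and -0.06, camera adjusted p = 0.0677 and 0.217). The list of myelinated mechanoreceptors did not pass (median 0.25, mean -0.15, test direction down, camera adjusted p = 0.747).

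Among the markers of other cells, 12 of 20 myelinating Schwann cell genes fell and 18 fell adjusted over the list alone, including Mbp and the periaxin gene Prx (-2.29 ± 0.40). The camera adjusted p was 1.3e-17, and the adjusted p = 0.036 with an estimated correlation. The list took 0.340 ± 0.0743 percent of counts after PTX and 1.10 ± 0.309 percent after vehicle. Satellite glial markers fell in 10 of 23 cases, and adjusted over the list alone in 19 with 1 higher (median -1.71, camera adjusted p = 3.06e-12, and an adjusted p = 0.121 with an estimated correlation). They included the glial transcription factor gene Sox10 (-2.74 ± 0.46) and the endothelin receptor gene Ednrb (-2.21 ± 0.41), and their share of counts was 1.07 ± 0.583 percent against 3.33 ± 0.849 percent. Of 23 macrophage markers 2 fell, 5 adjusted over the list alone (median -2.27, camera adjusted p = 6.03e-10, and an adjusted p = 0.163 with an estimated correlation). These 2 were Aif1 (-5.35 ± 1.25) and the complement gene C1qb (-4.63 ± 1.12). Fibroblast markers fell in 5 of 17 cases and 9 adjusted over the list alone, such as Lum, Col1a2 (-3.08 ± 0.51) and Dcn (-3.29 ± 0.59). Their camera adjusted p was 2.17e-10, and the adjusted p = 0.050 with an estimated correlation. No member passed among neutrophil markers (median -1.78, camera adjusted p = 7.28e-05, and an adjusted p = 0.332 with an estimated correlation), of which S100a8 and S100a9 were the most abundant. S100a8 stood at 15773 ± 16948 CPM after PTX and 50407 ± 27005 CPM after vehicle. The neutrophil list took 4.40 ± 4.62 percent of counts after PTX, with 0.562 and 1.05 percent in replicates 1 and 2 of the earlier date and 10.5 and 5.52 percent in replicates 3 and 4 of the later one, and 13.1 ± 5.32 percent after vehicle. Endothelial (median -2.05) and mural (median -1.51) markers fell as lists without a called member, with camera adjusted p-values of 0.00043 and 0.00098, and adjusted p = 0.130 and 0.223 with an estimated correlation. The neutrophil call was lost with the glial (median -2.22, camera adjusted p = 0.116) and neuron covariates (0.64, 0.231), and the mural call with the glial (with a positive median, 0.172) and neutrophil covariates (-0.78, 0.0998). Lymphocyte (median -1.61) and red cell (median -0.40) markers did not pass, with camera adjusted p-values of 0.0851 and 0.611.

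**Figure D2:**
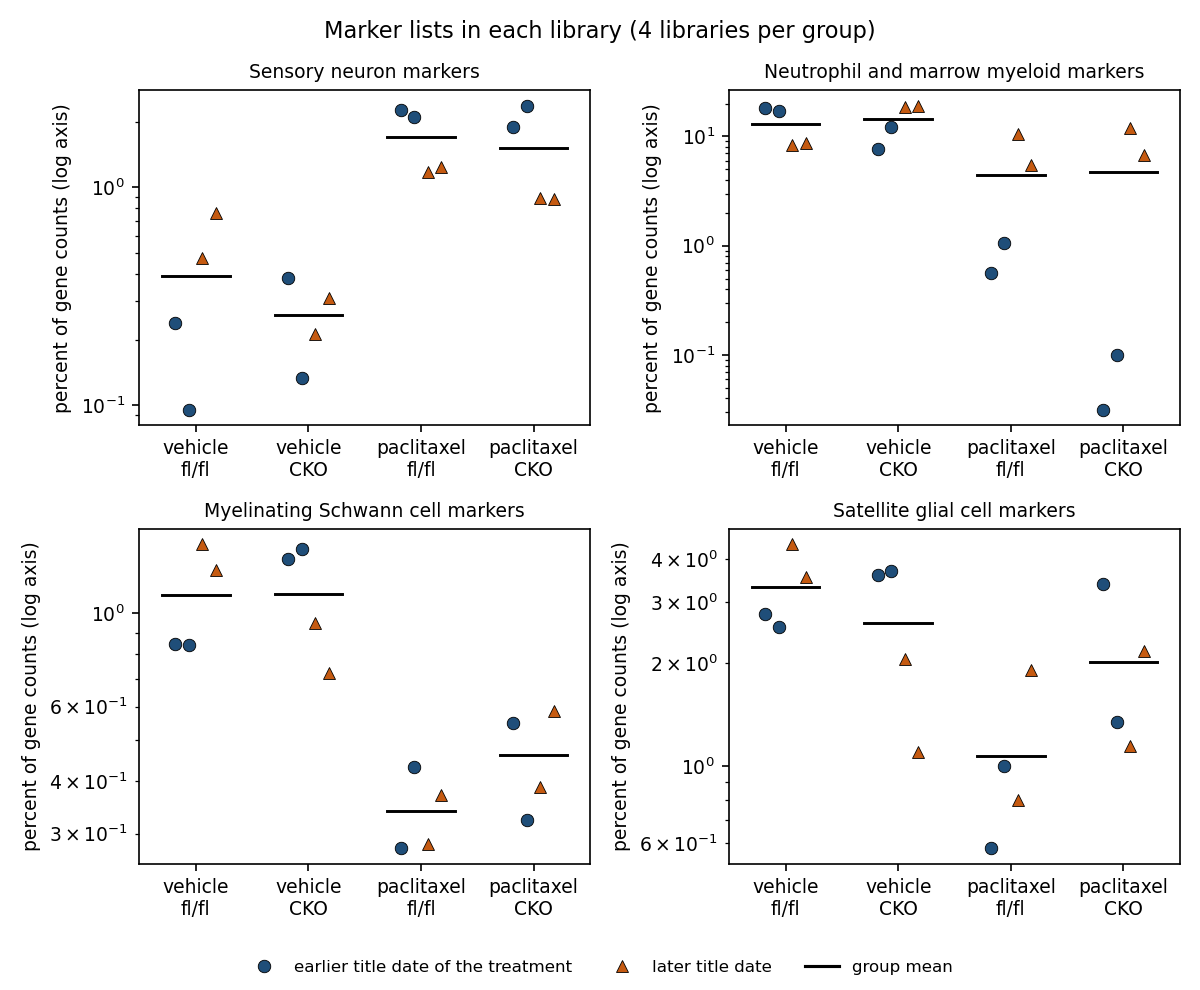
Share of each library's gene counts taken by marker lists of sensory neurons and other cell types, in percent on a log axis, by treatment and genotype label, where points are libraries and bars are group means. Pan-neuronal markers average 1.70 and 1.51 percent in the PTX groups and 0.392 and 0.260 percent in the vehicle groups, and neutrophil markers 4.40 and 4.74 percent against 13.1 and 14.4 percent.

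The lists of microtubule, synaptic vesicle and channel genes were higher after PTX at the preset correlation and did not pass with an estimated one. Of 49 tubulins and microtubule-associated genes, the class to which the drug's binding target belongs, 19 rose and none fell, 25 adjusted over the list alone. They included the dynactin gene Dctn1 (1.97 ± 0.30), the tubulin genes Tubb5 (1.46 ± 0.25) and Tubb2a (2.49 ± 0.46) and the kinesin gene Kif5a (2.85 ± 0.53). The list gave a camera adjusted p of 7.19e-11, and an adjusted p = 0.121 with an estimated correlation. Of 30 genes of the synaptic vesicle machinery, 12 rose and none fell, or 19 and 1 adjusted over the list alone. Vamp2, a vesicle fusion protein, rose by 1.75 ± 0.25, from 173 ± 49.7 to 580 ± 104 CPM (edgeR adjusted p = 0.0040), and Syn1, a vesicle phosphoprotein, by 2.83 ± 0.49. Here the camera adjusted p was 4.95e-14, and the adjusted p = 0.121 with an estimated correlation. Sodium channel subunits rose in 3 of 14 cases (7 adjusted over the list alone), Scn10a, Scn9a and Scn4a, with a camera adjusted p of 7.2e-05 and an adjusted p = 0.130 with an estimated correlation. Calcium, HCN and TRP channel genes rose in 5 of 39 cases (9 adjusted over the list alone), among them Trpv1 and P2rx2, the ATP-gated channel subunit, with a camera adjusted p of 2.16e-05 and an adjusted p = 0.122 with an estimated correlation. Potassium channel genes gave 2 up and 1 down of 43, and the same adjusted over the list alone (median 1.91, camera adjusted p = 3.05e-06, and an adjusted p = 0.121 with an estimated correlation). Kcnt1, a sodium-activated channel, rose by 3.03 ± 0.60, and Kcna1 fell by 2.08 ± 0.35, from 402 ± 57.4 to 94.7 ± 21.4 CPM. Of 25 genes of inhibitory receptor signalling 2 rose, the G protein gene Gnao1 (2.72 ± 0.58) and its regulator Rgs4 (2.99 ± 0.81), 3 adjusted over the list alone (camera adjusted p = 9.49e-05, and an adjusted p = 0.121 with an estimated correlation). With the neuron covariate the calls of the sodium (median 0.31, camera adjusted p = 0.507), potassium (0.48, 0.507), calcium, HCN and TRP (0.45, 0.179) and inhibitory receptor lists (0.18, 0.832) were lost, and with the glial covariate those of the sodium (0.63, 0.228), calcium, HCN and TRP (1.14, 0.0714) and inhibitory receptor lists (1.52, 0.114).

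Injury and growth genes gave 8 up and none down of 32, or 10 and 1 adjusted over the list alone (median 0.96, camera adjusted p = 0.0058, and an adjusted p = 0.121 with an estimated correlation). Lifr, Gap43 and Stat3, a cytokine receptor, a growth cone protein and a transcription factor, rose by 2.07 ± 0.36, 2.52 ± 0.60 and 1.00 ± 0.24. Neurotrophin receptors and ligands moved both ways, with 5 up and 2 down of 23, or 8 and 3 adjusted over the list alone. The nerve growth factor receptor gene Ngfr rose by 2.65 ± 0.45, and Ret and Ntrk2 are given above. As a list they did not pass (median -0.27, mean 0.14, test direction up, camera adjusted p = 0.149). Sterol synthesis genes rose in 3 of 24 cases, and as many adjusted over the list alone, with Acat2 up by 1.60 ± 0.36 (camera adjusted p = 0.0013, and an adjusted p = 0.318 with an estimated correlation). The injury call was lost with the glial covariate (median 0.60, camera adjusted p = 0.0675) and the sterol call with the neuron covariate (0.18, 0.131). Respiratory chain genes held no call in 72 (median 0.13, camera adjusted p = 0.303). Unfolded protein response genes gave 1 up and 1 down of 24, and the same adjusted over the list alone, Asns (2.18 ± 0.51) and Ddit4 (-1.72 ± 0.45), without passing as a list (camera adjusted p = 0.410). The genes flanking Scn10a on its chromosome held no call in 26 (median 0.03, camera adjusted p = 0.735).

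Of the immune signalling lists, 4 were lower after PTX at the preset correlation, with few members called and none passing with an estimated one. Of 25 genes of the lymphotoxin-beta receptor and NF-kB pathway 2 fell, and 2 adjusted over the list alone, Ltbr and the chemokine gene Cxcl12 (-3.75 ± 0.87). Their median was -0.80 (camera adjusted p = 0.00057, and an adjusted p = 0.318 with an estimated correlation). The call was lost without the 4 libraries of the earlier PTX date (median -0.15, camera adjusted p = 0.216) and with the glial covariate (-0.26, 0.337). It was also lost, with a positive median, with the neutrophil covariate (0.14, camera adjusted p = 0.518) and the neuron covariate (0.60, camera adjusted p = 0.213). Of 53 cytokine and chemokine genes 1 fell, the prostaglandin synthase gene Ptges (-2.07 ± 0.58), and none adjusted over the list alone (median -1.39, camera adjusted p = 7.67e-08, and an adjusted p = 0.130 with an estimated correlation). Antigen presentation genes fell in 1 of 20 cases, B2m (-1.35 ± 0.38), and 10 adjusted over the list alone (median -1.41, camera adjusted p = 6.02e-07, and an adjusted p = 0.130 with an estimated correlation). Interferon response genes gave 1 up of 32, Stat2 (2.03 ± 0.44), and 1 up and 3 down adjusted over the list alone, while the list was lower (median -0.94, camera adjusted p = 0.0125, and an adjusted p = 0.332 with an estimated correlation). That call was lost without replicate 2 of vehicle fl/fl (camera adjusted p = 0.139) and without the earlier PTX date (camera adjusted p = 0.151). Immediate-early and heat shock genes, which rise when tissue is dissociated, gave 2 up and 1 down of 30, or 2 and 2 adjusted over the list alone, with Hsp90aa1 up by 1.19 ± 0.32 and Dusp6 down by 1.46 ± 0.39. The list was lower (median -1.15, camera adjusted p = 0.00053, and an adjusted p = 0.223 with an estimated correlation). Cell cycle and ribosomal protein genes were lower as lists with no member called (medians -1.65 and -0.37, camera adjusted p = 0.00025 and 0.0058, and adjusted p = 0.318 and 0.351 with an estimated correlation). With the neuron covariate the calls of the cytokine (median -0.66, camera adjusted p = 0.125), antigen presentation (-0.34, 0.167), interferon (0.03, 0.680), immediate-early (0.08, 0.890) and cell cycle lists (0.26, 0.957) were lost. The immediate-early call was also lost with the glial (0.27, 0.555) and neutrophil covariates (-0.29, 0.0674), and the cell cycle call with the neutrophil covariate (-0.16, 0.320).

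By size, the largest rises with values that did not overlap were in genes near 0 after vehicle. P2rx2, Sectm1b, Dgkk, Cacna1i, Cldn9 and Scn4a had 0 counts over the vehicle group and were at least 185-, 151-, 149-, 124-, 113- and 96.7-fold higher against a floor of 3 counts over the group. Prokr2, a prokineticin receptor, had 28.1 ± 10.7 CPM against 0.029 CPM, a count ratio of 1171 (95 percent counting interval 210 to 46272, edgeR adjusted p = 0.0052). Chrna4, a nicotinic receptor subunit, and Chst10, a sulfotransferase, had count ratios of 954 (171 to 37709) and 485 (86.7 to 19200). The falls chosen by the same rule follow. Il21r and Mfap2 had 0 counts after PTX and were at least 241- and 99.5-fold lower, and Bmp5 had a count ratio of 251 in favour of vehicle (85.4 to 1218). Cbr2, the growth factor gene Igf1, the microglial gene Fcrls, the nucleotide receptor gene P2ry6 and the lipid transporter gene Abca9 fell, with log2 fold changes of -7.25 ± 1.88, -7.05 ± 1.86, -6.32 ± 1.68, -5.63 ± 1.55 and -4.79 ± 0.95. Apod, an apolipoprotein, fell by 4.85 ± 0.78, from 2834 ± 2002 to 98.5 ± 60.9 CPM (edgeR adjusted p = 0.0058).

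For fl/fl, 704 genes compares with 2776 at an unadjusted threshold of 0.05, 1626 by DESeq2 and 5279 by limma-voom. The 454 higher and 250 lower genes became 893 and 733 by DESeq2, 2663 and 2616 by limma-voom, 370 and 290 with upper-quartile scaling and 244 and 231 with the compared groups alone, so the excess of rises depends on these choices. The count fell to 177 without replicate 1 of PTX fl/fl, 206 without its replicate 2, and 263, 307 and 449 without replicates 1, 2 and 3 of vehicle fl/fl. It fell to 4 without the 4 libraries of the earlier PTX date, and to 0 with the neuron or the glial marker mean as a covariate and 245 with the neutrophil one. The lists called, 27 of 34, became 14 with the neuron covariate and 15 with the glial one, and the neutrophil covariate kept 22 of the 26 it could test. Of the 64 called genes named for this comparison, leaving out 1 library ended the call of 10 to 34.

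**Figure D3:**
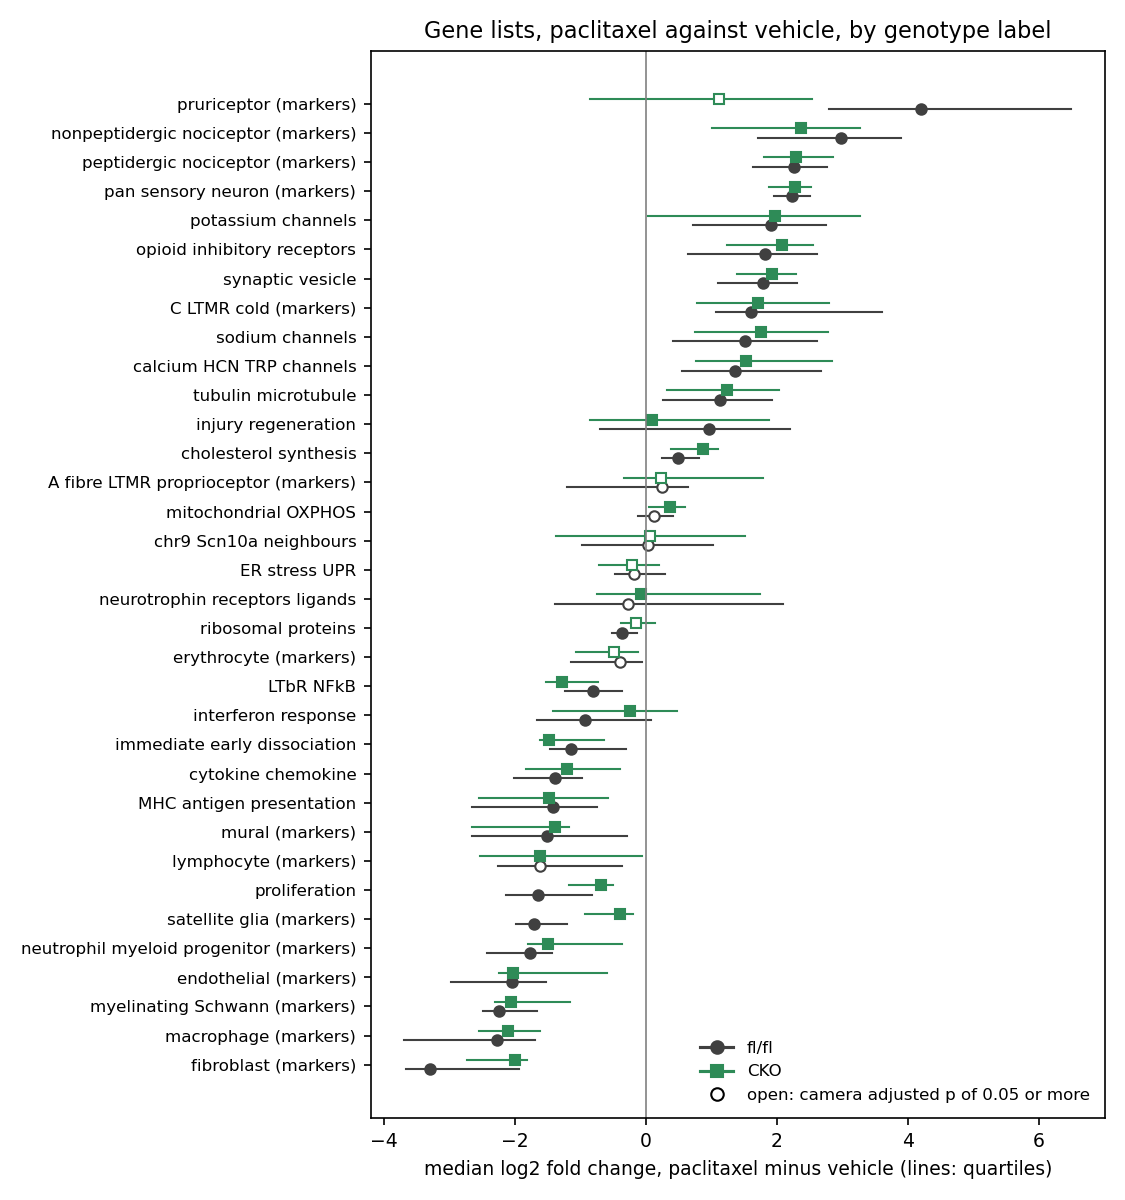
Median log2 fold change of each of the 34 gene lists for PTX against vehicle, with lines from the lower to the upper quartile, for fl/fl (circles) and CKO (squares), open where the camera adjusted p is 0.05 or more. The pan-neuronal medians are 2.23 and 2.28, the Schwann cell medians -2.24 and -2.06, and the satellite glial medians -1.71 and -0.40.

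The next comparison asked what PTX changed in mice labelled CKO. The genes called higher again included neuron genes, and those called lower Schwann cell genes. Ngfr, the low-affinity neurotrophin receptor, rose by 3.43 ± 0.47, from 59.98 ± 21.7 to 649 ± 332 CPM (edgeR adjusted p = 0.0029), and Bdnf, a neurotrophin, by 4.11 ± 0.85, from 7.58 ± 5.17 to 131 ± 71.5 CPM (edgeR adjusted p = 0.020). Vamp2 rose by 1.65 ± 0.25 (edgeR adjusted p = 0.0059). Mbp fell by 2.02 ± 0.32, from 2561 ± 325 to 632 ± 237 CPM (edgeR adjusted p = 0.0071). In all, 366 genes passed at an edgeR adjusted p under 0.05, 315 higher and 51 lower. The groups did not overlap for 1910 genes, 13.5 percent, where chance gives 2.86 percent.

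In CKO, pan-neuronal markers rose in 8 of 16 cases, 15 adjusted over the list alone, with Slc17a6 (2.60 ± 0.52), a vesicular glutamate transporter, Uchl1 (2.30 ± 0.46) and Prph (2.53 ± 0.52). The camera adjusted p was 2.01e-12, and the adjusted p = 0.168 with an estimated correlation. The list took 1.51 ± 0.745 percent of counts after PTX and 0.260 ± 0.109 percent after vehicle. Peptidergic markers rose in 4 of 14 cases, 11 adjusted over the list alone, with Calca (2.40 ± 0.50) and Adcyap1 (2.09 ± 0.41), and non-peptidergic markers in 1 of 17, Ret (3.22 ± 0.53), and 2 adjusted over the list alone. Their camera adjusted p-values were 4.65e-10 and 8.72e-06, and adjusted p = 0.129 and 0.210 with an estimated correlation. Markers of C low-threshold mechanoreceptors rose as a list with no call, 2 adjusted over the list alone (camera adjusted p = 0.0021, and an adjusted p = 0.168 with an estimated correlation). Neither pruriceptor markers (median 1.12, none called, 4 up adjusted over the list alone, camera adjusted p = 0.153) nor those of myelinated mechanoreceptors passed. The latter gave 1 down of 24, Kcna1 (-1.87 ± 0.35), and 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.425). The non-peptidergic call was lost with the neuron covariate, where the median turned to -1.05 (camera adjusted p = 0.772), and with the glial covariate (1.09, 0.128), and so was the C low-threshold call (0.17, 0.0956, and 0.82, 0.0692).

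Tubulin and microtubule genes of CKO rose in 18 of 49 cases (25 up and 1 down adjusted over the list alone), with Dctn1 (1.91 ± 0.30), Mtap1b (2.10 ± 0.39), the older symbol of Map1b, and Tubb5 (1.28 ± 0.25), and synaptic vesicle genes in 11 of 30 (17 adjusted over the list alone), with Vamp2 and Syn1 (2.54 ± 0.48). The camera adjusted p-values were 6.12e-10 and 1.63e-13, and adjusted p = 0.168 with an estimated correlation for both. Sodium channel genes gave 1 up of 14, Scn10a, and 6 adjusted over the list alone, and potassium channel genes 3 up and 1 down of 43, or 14 and 1 adjusted over the list alone, with Kcnab2 up by 1.97 ± 0.36. Calcium, HCN and TRP channel genes had no call in 39 and 5 adjusted over the list alone, and inhibitory receptor genes 1 up of 25, Gnao1 (2.63 ± 0.58), and 1 adjusted over the list alone. These channel and receptor lists passed with camera adjusted p-values of 0.00013, 3.3e-06, 2.71e-06 and 0.00020, and adjusted p = 0.177, 0.168, 0.168 and 0.168 with an estimated correlation. With the neuron covariate these 4 calls were lost, with medians of 0.31, 0.61, 0.28 and -0.15 and camera adjusted p-values of 0.915, 0.464, 0.108 and 0.915 in the same order.

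Injury genes of CKO gave 5 up of 32, or 11 up and 1 down adjusted over the list alone, among them Bdnf and the heat shock gene Hspb1 (1.85 ± 0.35), with a list median of 0.09 (camera adjusted p = 0.0289, and an adjusted p = 0.168 with an estimated correlation). Neurotrophin receptors and ligands rose in 3 of 23 cases, 7 adjusted over the list alone (median -0.07, mean 0.30, test direction up, camera adjusted p = 0.043, and an adjusted p = 0.255 with an estimated correlation). Sterol synthesis genes gave 1 up of 24, Acat2 (1.99 ± 0.37), and 8 adjusted over the list alone (camera adjusted p = 3.75e-05, and an adjusted p = 0.210 with an estimated correlation). Respiratory chain genes rose as a list with none of 72 called (median 0.37, camera adjusted p = 0.00645, and an adjusted p = 0.582 with an estimated correlation), and lost the call without replicate 2 of PTX CKO (camera adjusted p = 0.114). The injury call was lost without replicate 4 of PTX CKO or replicate 1 of vehicle CKO (camera adjusted p = 0.0721 and 0.0719). That of the neurotrophin list was lost without replicate 1 or 4 of PTX CKO (0.0656 and 0.119) or replicate 2, 3 or 4 of vehicle CKO (0.0515, 0.0594 and 0.171). The injury call was lost with the glial covariate (camera adjusted p = 0.0692), the respiratory chain call with the glial (0.464), neutrophil (0.517) and neuron covariates (0.915), and the neurotrophin call with the neutrophil (0.0558) and neuron covariates (0.259). Ribosomal protein, unfolded protein response and Scn10a-flanking genes did not pass (camera adjusted p = 0.142, 0.161 and 0.828), with 1 flanking gene up adjusted over the list alone.

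Schwann cell markers fell in 8 of 20 cases in CKO and 16 adjusted over the list alone, including Mbp, the claudin gene Cldn19 (-3.44 ± 0.76), Pllp (-3.34 ± 0.66) and the transcription factor gene Egr2 (-2.19 ± 0.52). This was the 1 list that kept its call with an estimated correlation (camera adjusted p = 4.73e-17, and the adjusted p = 0.048 with an estimated correlation), and its share of counts was 0.461 ± 0.127 percent against 1.11 ± 0.331 percent. Satellite glial markers had 1 down of 23, Ednrb (-1.84 ± 0.41), and 1 up and 2 down adjusted over the list alone (median -0.40, camera adjusted p = 0.0068, and an adjusted p = 0.453 with an estimated correlation), and lost the list call without replicate 3 of PTX CKO (camera adjusted p = 0.0887). Their share was 2.01 ± 1.02 percent against 2.61 ± 1.26 percent. Fibroblast markers fell in 4 of 17 cases, 7 adjusted over the list alone, with the matrix genes Ogn (-2.18 ± 0.42) and Col3a1 (-2.92 ± 0.64), with a camera adjusted p of 1.41e-07 and an adjusted p = 0.143 with an estimated correlation. Macrophage (median -2.11), neutrophil (median -1.49), mural (median -1.38), lymphocyte (median -1.62) and endothelial (median -2.03) markers fell as lists with none called, and 2 mural genes fell adjusted over the list alone. Their camera adjusted p-values were 2.45e-09, 1.74e-06, 2.95e-06, 0.0225 and 0.0289, and adjusted p = 0.175, 0.255, 0.168, 0.210 and 0.331 with an estimated correlation. The lymphocyte call was lost without replicate 1 of PTX CKO (0.0712) or 4 of vehicle CKO (0.0543), and the endothelial call without replicate 1 or 3 of PTX CKO (0.0789 and 0.0506) or 1 or 4 of vehicle CKO (0.171 and 0.0902). With the neuron covariate the satellite glial (median -0.18, camera adjusted p = 0.772), neutrophil (0.18, 0.915), lymphocyte (0.53, 0.83) and endothelial (-1.24, 0.0975) calls were lost, with the glial covariate the mural (0.55, 0.260) and lymphocyte calls (camera adjusted p = 0.0587 for the latter), and with the neutrophil covariate the lymphocyte (-1.28, 0.589) and endothelial calls (-1.64, 0.0901). The neutrophil list took 4.74 ± 5.80 percent of counts after PTX, with 0.0316 and 0.0993 percent on the earlier date, and 14.4 ± 5.55 percent after vehicle. Red cell markers did not pass (camera adjusted p = 0.380).

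The immune signalling lists were also lower in CKO at the preset correlation, with 1 member called among them and none passing with an estimated one. The lymphotoxin-beta receptor and NF-kB list had no call in 25 and 1 down adjusted over the list alone (median -1.28, camera adjusted p = 1.67e-06, and an adjusted p = 0.175 with an estimated correlation). That call was lost with the neutrophil covariate (median -0.41, camera adjusted p = 0.0565) and the neuron covariate (camera adjusted p = 0.772). Cytokine (median -1.21) and antigen presentation (median -1.48) genes had no call and camera adjusted p-values of 2.37e-06 and 5.34e-06, each with an adjusted p = 0.175 with an estimated correlation. Immediate-early genes gave 2 up and 2 down of 30, Egr2 and Dusp6 (-1.61 ± 0.40) being the falls and the heat shock genes Hsp90aa1 (1.39 ± 0.32) and Hspa8 (1.08 ± 0.27) the rises, or 4 and 10 adjusted over the list alone (median -1.48, camera adjusted p = 5.34e-06, and an adjusted p = 0.168 with an estimated correlation). Interferon response genes fell in 1 of 32 cases, Oas2 (-4.80 ± 1.21), an antiviral enzyme, or 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.0289, and an adjusted p = 0.395 with an estimated correlation). The interferon call was lost without replicate 3 or 4 of PTX CKO (0.0724 and 0.124) or replicate 4 of vehicle CKO (0.0741). Cell cycle genes were lower as a list (median -0.68, camera adjusted p = 0.0024, and an adjusted p = 0.395 with an estimated correlation), a call lost without replicate 1 of PTX CKO (0.0581). With the neuron covariate the calls of the cytokine (median -0.28, camera adjusted p = 0.292), antigen presentation (-0.34, 0.453), interferon (0.23, 0.772), immediate-early (-0.37, 0.365) and cell cycle lists (0.40, 0.772) were lost. So were that of the immediate-early list with the glial covariate (-0.46, 0.0910) and those of the cytokine (-0.49, 0.109) and cell cycle lists (0.41, 0.393) with the neutrophil covariate.

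The largest rises in CKO were again in genes with 0 counts after vehicle. Epn3 (28.4 ± 33.3 CPM), Lrguk, Prokr2 (16.9 ± 9.55 CPM), the channel gene Trpc7, the phosphatase gene Ptpn5, Pcdha9, Spink2, Celf3 and Immp2l were at least 334-, 218-, 199-, 182-, 143-, 120-, 95.5-, 84.9- and 66.6-fold higher. Odz1, the older symbol of the teneurin gene Tenm1, had a count ratio of 586 (95 percent counting interval 105 to 23165). Toward vehicle, the count ratios were 658 for the nucleotide receptor gene P2ry13 (182 to 5442), 661 for the interferon-induced gene Epsti1 (118 to 26155), 424 for the claudin gene Cldn11 (75.7 to 16801) and 208 for Ifi203 (70.9 to 1013). Oas2, the scavenger receptor gene Cd36 (-3.71 ± 0.85), Cldn19, Pllp, Lst1 (-3.22 ± 0.79) and the erythroid membrane gene Gypc (-3.05 ± 0.78) followed.

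For CKO, 366 genes compares with 2793 at an unadjusted threshold of 0.05, 1446 by DESeq2 and 2695 by limma-voom. The 315 higher and 51 lower genes became 943 and 503 by DESeq2 and 1259 and 1436 by limma-voom, where falls outnumbered rises. The count was 68 and 30 without replicates 1 and 2 of PTX CKO and 209, 36 and 97 without replicates 1, 2 and 3 of vehicle CKO. It was 159 with the compared groups fitted alone, 0 without the 4 libraries of the earlier PTX date, and 1, 12 and 2 with the glial, neutrophil or neuron marker mean as a covariate. The neuron and Schwann cell marker means did not overlap between treatments in CKO either. Without that date the list calls were lost for respiratory chain (median -0.03, camera adjusted p = 0.799), neurotrophin (0.0509), cell cycle (0.963), lymphocyte (0.523), neutrophil (0.0945) and endothelial genes (0.185), and 10 lists were called with the neuron covariate. The neutrophil covariate kept 20 of the 27 called lists it could test. Of the 47 called genes named for this comparison, leaving out 1 library ended the call of 5 to 39.

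The responses to PTX in the 2 genotype labels shared genes. Of the genes called in each, 216 were higher and 29 lower in both, and none moved in opposite directions. Independent lists of those sizes would share 10.1 and 0.898, but the 2 comparisons share title dates, and the deviations from the group mean of same-numbered PTX libraries of the 2 labels correlated (0.37, 0.40, 0.39 and 0.22), so this is not the overlap without a shared response to treatment. Of the 704 genes called in fl/fl, 703 had the same sign in CKO, and of the 366 called in CKO 364 had the same sign in fl/fl. Across the 14200 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.523 and a Spearman rho of 0.637. The comparisons share no library. The number of shared genes was 527 at an adjusted p of 0.1 and 16 at 0.01.

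The comparison of genotype labels among PTX libraries asked whether loss of the receptor changed the treated state. No gene passed edgeR's test, with or without a date block. Under an unadjusted 0.05 lay 266 genes, where chance gives 710. DESeq2 called 18 and limma-voom 0. Date spread, not in the main fit, can lower such counts, so 266 does not show equality. Of genes with the smallest p, none called, the lactonase Pon2 (78.9 ± 19.1 against 28.2 ± 11.5 CPM, log2 1.48 ± 0.38), Afap1l2 (1.93 ± 0.49) and the zinc transporter Slc39a1 (1.25 ± 0.32) were higher. P2ry13 (count ratio 123, 33.7 to 1020) and Sst (0.0949 ± 0.190 against 6.15 ± 3.29 CPM, log2 -5.82 ± 1.97) were lower. Each had an edgeR adjusted p of 1. The groups did not overlap for 292 genes, 2.06 percent (2.86 by chance).

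As a list, satellite glial markers were higher in PTX libraries labelled CKO, with 21 of 23 members positive and a median of 0.76 (camera adjusted p = 3.17e-12, and an adjusted p = 0.465 with an estimated correlation). No member was called, over all genes or adjusted over the list alone, and Apoe, the apolipoprotein E gene, stood at 11873 ± 5690 against 6350 ± 3518 CPM (log2 0.90 ± 0.40). The share of counts of this list was 2.01 ± 1.02 percent against 1.07 ± 0.583 percent, and the mean log2 CPM of its genes gave an exact permutation p = 0.143 (Benjamini-Hochberg adjusted p = 0.317 over 60 tests). Pruriceptor markers were lower, with 0 of 14 positive and a median of -1.32 (camera adjusted p = 0.00025, and an adjusted p = 0.465 with an estimated correlation), also with no member called. They included Sst and N28178, the older symbol of Phf24 (-0.51 ± 0.73). The lymphotoxin-beta receptor and NF-kB list did not differ by the test (median -0.30, camera adjusted p = 0.898), with Nfkbia, an NF-kB inhibitor, at -0.33 ± 0.88 and Tnfaip3, another, at -0.44 ± 1.10. The number of lists called was 2, and it was 5, 9 and 4 without replicates 2, 3 and 4 of PTX fl/fl and 9, 13, 4 and 9 without replicates 1 to 4 of PTX CKO. It was 11 with the neutrophil marker covariate, 4 with the neuron one or with the date as a block, and 10 without the earlier PTX date.

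Genes changed by PTX were also followed across genotype. Of the 704 genes called for PTX in fl/fl, 93.0 percent had the opposite sign in CKO against fl/fl under PTX. The PTX fl/fl libraries stand in both comparisons. For the 500 genes of smallest p the share was 95.0 percent, and 87.8 percent (85.2 to 90.8) in 20 simulations with unchanged groups. The covariance of the 2 sets of log2 fold changes was -0.682, and -0.730 in the simulations (-0.764 to -0.698). The simulations held no treatment or date effect, so a value beyond their range does not show reversal by genotype. With the PTX fl/fl libraries split so that none was shared, replicates 1 and 2 in the treatment comparison gave 34.5 percent over 945 genes. Replicates 3 and 4 gave 85.7 percent over 7. Replicates 1 and 2 have the earlier date, and 1268 genes were called between the dates within PTX. Both shares thus carry date as well as genotype.

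In vehicle libraries, 3 genes were lower in those labelled CKO than in those labelled fl/fl. Bend6, a BEN-domain transcriptional regulator, stood at 0.080 ± 0.10 against 21.1 ± 13.7 CPM, 3 counts against 930 and a count ratio of 262 (95 percent counting interval 89.3 to 1272), with an edgeR adjusted p of 0.0022. Slc29a4, a monoamine transporter, stood at 0.22 ± 0.14 against 10.96 ± 10.5 CPM (log2 -5.54 ± 0.85, edgeR adjusted p = 0.039). Sbk1, a protein kinase, stood at 2.21 ± 0.94 against 19.1 ± 5.06 CPM (-3.11 ± 0.49, edgeR adjusted p = 0.040). No gene was higher by the test, and the smallest p-values in that direction belonged to Psd3 (2.10 ± 0.46, edgeR adjusted p = 0.62), Med20 (1.35 ± 0.36) and Zik1 (count ratio 340, 93.8 to 2817). Neuron markers took 0.260 ± 0.109 percent of counts in CKO and 0.392 ± 0.291 percent in fl/fl, and the mean log2 CPM of the list gave an exact permutation p of 0.743. With these 3 among them, 655 genes lay under an unadjusted 0.05, where chance gives 710. DESeq2 called 108, these 3 included, and limma-voom 0, and the groups did not overlap for 354 genes, 2.49 percent. Only 1 gene remained without replicate 2, 3 or 4 of vehicle fl/fl or replicate 2 or 3 of vehicle CKO, and 15 were called without replicate 4 of vehicle CKO. Over its alternatives Bend6 lost the call in 5 of 23, with edgeR, DESeq2 and limma adjusted p-values from 2.8e-12 to 1.00, Slc29a4 in 12 of 21 (1.1e-07 to 0.900) and Sbk1 in 17 of 23 (2.1e-09 to 1.00). Sbk1 kept it without replicate 4 of vehicle CKO alone among the single libraries, and Slc29a4 without that library or replicate 1 of vehicle fl/fl.

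Respiratory chain genes were lower as a list in vehicle libraries labelled CKO, with 6 of 72 positive and a median of -0.25 (camera adjusted p = 0.00997, and an adjusted p = 0.994 with an estimated correlation). No member was called, and the most abundant, Atp5b and Atp5a1 of the ATP synthase, were at -0.10 ± 0.25 and -0.51 ± 0.25. The list lost its call without replicate 1 or 4 of vehicle fl/fl (0.118 and 0.0806) or replicate 1 or 4 of vehicle CKO (0.114 and 0.0982), and with the neuron covariate (0.0640), while 9 lists were called without replicate 2 of vehicle fl/fl. The lymphotoxin-beta receptor and NF-kB list did not pass (median 0.21, camera adjusted p = 0.175), with Nfkbia at 0.32 ± 0.88 and Tnfaip3 at 0.08 ± 1.10.

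The interaction asked whether the response to PTX differed by genotype label. Bend6 passed, with a difference of 7.28 ± 1.07 on the log2 scale (edgeR adjusted p = 0.045), and 475 genes lay under an unadjusted 0.05, with 59 calls by DESeq2 and 0 by limma-voom. Bend6 lost the call in 22 of 28 alternatives, with adjusted p-values from 8.5e-08 to 1.00, and of the single libraries it was kept without replicate 2 of vehicle fl/fl and replicate 4 of vehicle CKO alone. The count of 1 became 0 without any 1 of 13 libraries and 4 without replicate 4 of vehicle CKO. The 1 gene called without replicate 1 of vehicle fl/fl was another gene (Bend6 at an edgeR adjusted p of 0.0593). It also became 0 under the other normalizations, the blocks, the glial and neutrophil covariates and without the earlier PTX date. Epsti1 (-7.40 ± 1.67), Psd3 (-2.60 ± 0.63), Ciapin1 (-1.57 ± 0.44) and Apoe (1.34 ± 0.57) did not pass, with edgeR adjusted p-values of 1.00. Satellite glial markers were higher as a list, with 22 of 23 positive and a median of 0.90 (camera adjusted p = 5.14e-08, and an adjusted p = 0.961 with an estimated correlation). Pruriceptor markers were lower, with 3 of 14 positive and a median of -1.44 (camera adjusted p = 0.0063, and an adjusted p = 0.961 with an estimated correlation), a call lost without replicate 2 of vehicle CKO (camera adjusted p = 0.0724). For Ltbr and the lists that passed for PTX in 1 genotype label alone, pruriceptor markers apart, the interaction was not called. Ltbr was at 0.65 ± 0.71 (edgeR adjusted p = 1.00), and the camera adjusted p was 0.289 for respiratory chain, 0.367 for ribosomal protein, 0.806 for neurotrophin and 0.806 for lymphocyte genes. The lymphotoxin-beta receptor and NF-kB list had a median of -0.33 (camera adjusted p = 0.339). The 2 lists called became 5 without replicate 1 of PTX fl/fl, 6 and 7 without replicates 3 and 4 of PTX CKO, 4 without replicate 2 of vehicle fl/fl and 1 without replicate 2 of vehicle CKO.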

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

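The tests chosen after the result was seen were those of the neuron share, of 1 common change for all other cells, of dilution by neutrophil RNA and of the title date for the PTX response, that of neuron content for the 3 vehicle genes, and the splits with balanced dates.

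In 32 of 489 groups of 4 libraries (6.54 percent, where chance gives about 5 percent, 1 in 20), 1 library lay apart from the other 3 by more of the range than Dixon's critical value for 4 samples allows. The gap over the range follows each item. In PTX fl/fl, replicate 3 was highest for Dcn 0.914, Fcrls 0.869, Ifi203 0.844, Igf1 0.917, P2ry13 0.956 and P2ry6 0.952 and lowest for Ptpn5 0.847, and replicate 4 was lowest for Aif1 0.849. In PTX CKO, replicate 4 was highest for the endothelial share of counts 0.928, Epn3 0.830, Fcrls 0.841, Igf1 0.964 and Spink2 0.838, and replicate 3 was highest for Il21r 1.000 and lowest for Cldn9 0.869. In vehicle fl/fl, replicate 4 stood apart for the fibroblast share 0.886, Apod 0.944, Dcn 0.847 and Spink2 0.921, replicate 3 for Ednrb 0.831 and Ntrk2 0.847, and replicate 1 for Oas2 0.840. In vehicle CKO, replicate 1 stood apart for Abca9 0.958, Asns 0.964, Cbr2 0.947, Chrna4 0.894, Fcrls 0.840 and Gap43 0.837, replicate 2 for Dgkk 0.893, replicate 3 for Adcyap1 0.876 and Cldn9 0.990, and replicate 4 for P2rx2 1.000.

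The response to PTX differed between the genotype labels by the interaction term for Bend6 (7.281) and for the pruriceptor (-1.438) and satellite glial (0.8966) lists. Bend6 lost this call in 22 of 28 alternatives, both lists lost it with an estimated correlation (adjusted p = 0.961), and the splits below do not exclude chance for the count of genes.

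Of 35 splits of the 8 fl/fl libraries, only the real 1 called as many as 704 genes for PTX, the highest other split calling 0, and of 35 in CKO only the real 1 called as many as 366, the highest other calling 1. Libraries were treated as exchangeable, so at 1 of 35 chance between dates is not excluded. Between genotypes under PTX, 35 of 35 splits called at least the real 0, which a count of 0 makes certain and which therefore says nothing about chance. The split by title date called 1122 genes, which points to a structure of the samples by date. Between genotypes under vehicle 6 of 35 called at least 3 genes (highest other 14), and for the interaction 35 of 100 called at least 1 (highest other 628), so chance is not excluded there. These splits ignore date, and a count of 628 points to a structure of the samples. Among splits with 2 libraries of each date on each side, 1 of 18 called at least 3 genes under vehicle (highest other 2), and 18 splits are too few for a share under 0.05. For the interaction 13 of 100 called at least 1 (highest other 1), so chance is not excluded for it with the dates balanced either.

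Pan-neuronal and nociceptor marker lists were higher, and Schwann, satellite glial, macrophage, neutrophil and fibroblast lists lower, after PTX in both genotype labels at the preset correlation (the Schwann list alone in both with an estimated one, and 1 of 23 satellite glial and no macrophage or neutrophil gene called in CKO), and a candidate explanation is a larger share of neuron RNA in the sorted PTX cells. Neutrophil RNA dilution would raise all other RNA after PTX, and the Schwann cell list fell (median -2.2355 in fl/fl). In CKO, satellite glia (median -0.40199, quartiles -0.94 to -0.20) and Schwann cells (quartiles -2.30 to -1.15) argue against 1 common change for all other cells. In fl/fl, with a satellite median of -1.71, it stays open. Among PTX libraries alone, 91.193 percent of the genes called in fl/fl (642 of 704) had the same sign between the earlier and the later date, against 68.3 percent of all genes. All 15 neutrophil markers were also lower on the earlier date. Part of the pattern may be a mixture of cells that the sort for tracer would be expected to remove (pan-neuronal share 1.70 against 0.392 percent, 7 of the 16 pan-neuronal markers also in another list), and a change within neurons stays open, as do title date, of collection or of library preparation, and treatment, which cannot be told apart because 0 dates hold both. Without the earlier-dated PTX libraries the called genes had a median of 1.6127 in the direction called (1.97 before), which decides nothing, as they were chosen in a fit with these libraries and the later PTX date also held a larger neuron share (1.05 percent) than the vehicle dates (0.213 and 0.439 percent).

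Ltbr was not lower in libraries labelled CKO, and a candidate explanation is that its reads came from cells other than neurons, where a Nav1.8 Cre would leave the gene intact. Over 16 libraries its log2 CPM fell with the neuron marker mean (Pearson r = -0.80667, permutation p = 0.00016, Benjamini-Hochberg adjusted p = 0.00048, Spearman rho = -0.897), and r was -0.832 without the 2 farthest libraries. The relation was present within PTX (r = -0.830, exact permutation p = 0.0178, and -0.686 without 2) and not within vehicle (r = -0.0769, exact permutation p = 0.865), so part of the pooled value is the difference between treatments. An exchange of genotype labels stays open as well, with Ltbr higher in both CKO libraries on 2 of 4 dates, 1 of each treatment, where chance gives 9.34 percent, and lower in both on another. Reads outside the floxed exons were not separated here.

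Bend6, Slc29a4 and Sbk1 were lower in vehicle CKO than in vehicle fl/fl, and 1 candidate explanation is a lower neuron content. Against it as the whole cause, 2 of the 3 stayed called with the sensory neuron covariate (Bend6 -7.58, edgeR adjusted p = 0.00056, and Slc29a4 -5.34, edgeR adjusted p = 0.041), while Sbk1 at -3.01, before -3.11, did not pass (edgeR adjusted p = 0.073). Transcripts sampled from few neurons may give such losses. Of like-level genes assumed neuron-enriched, 3.5519 percent (13 of 366) had a median of 1 CPM or less in vehicle CKO. In reverse it was 2.46 percent (9 of 366), which decides nothing. An effect of the genotype was not excluded.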

How the results depend on the processing

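The tests without the 4 earlier-dated PTX libraries and with the neutrophil or the neuron covariate were chosen after the data were seen. Counts of genes and lists for which no alternative value is given below stayed within 1.5 times their value. The cause of the changes was not tested, except that the date alone, the compared groups alone and leaving out libraries use fewer samples by construction.

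Genes called for PTX in fl/fl, 704 in the main analysis, became 361 with the replicate block, 0 with the glial covariate, 245 with the neutrophil covariate, 0 with the neuron covariate, 4 without the earlier PTX date, 5279 by limma-voom and 1626 by DESeq2. In CKO, 366 became 126 with the replicate block, 159 with the compared groups alone, 1, 12 and 2 with the glial, neutrophil and neuron covariates, 0 without the earlier PTX date, 2695 by limma-voom and 1446 by DESeq2. Numbers do not pair the libraries of these comparisons, where the correlations of same-numbered libraries lay between -0.18 and 0.079, so the block removes degrees of freedom. For genotype under PTX DESeq2 called 18 and edgeR 0. For genotype under vehicle, 3 became 1 with the replicate block, the date block or the glial covariate, 0 with the earlier title date, the later title date or the compared groups alone, 0 without the earlier PTX date, 0 by limma-voom and 108 by DESeq2. The interaction's 1 gene became 0 with RLE or upper-quartile scaling, the replicate block, the date block, the glial or neutrophil covariate, without the earlier PTX date and by limma-voom, and 59 by DESeq2. The compared groups alone were not run for the interaction, which uses every group.

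Lists called with the estimated correlation were 3 of 27 for PTX in fl/fl, 1 of 28 in CKO, and 0 for genotype under PTX, genotype under vehicle and the interaction. The other changed counts of lists were, for PTX in fl/fl, 15 with the glial and 14 with the neuron covariate, and in CKO 10 with the neuron covariate. For genotype under PTX, 2 became 4 with the date block, 11 and 4 with the neutrophil and neuron covariates and 10 without the earlier PTX date. For genotype under vehicle, 1 became 5 with the glial covariate, 0 with the neuron covariate and 2 without the earlier PTX date, and for the interaction 2 became 5 with the date block, 5 with the glial covariate and 6 without the earlier PTX date. Of the called lists it could test, the glial covariate kept 14 of 25 for PTX in fl/fl and 19 of 26 in CKO, the neutrophil covariate 22 of 26 and 20 of 27, and the neuron covariate 13 of 26 and 9 of 27. The neutrophil covariate ended the lymphotoxin-beta receptor and NF-kB, immediate-early, cell cycle and mural calls in fl/fl (camera adjusted p 0.0674 to 0.518). In CKO it ended the lymphotoxin-beta receptor and NF-kB, cytokine, respiratory chain, neurotrophin, cell cycle, lymphocyte and endothelial calls (0.0558 to 0.589). The glial covariate ended 11 calls in fl/fl, those of the lymphotoxin-beta receptor and NF-kB, injury, sodium channel, calcium, HCN and TRP channel, inhibitory receptor, immediate-early, non-peptidergic, pruriceptor, C low-threshold, neutrophil and mural lists (camera adjusted p 0.0675 to 0.613), and 7 in CKO, those of the injury, respiratory chain, immediate-early, non-peptidergic, C low-threshold, lymphocyte and mural lists (0.0587 to 0.464). The neuron covariate ended 13 in fl/fl, those of the lymphotoxin-beta receptor and NF-kB, sodium, potassium and calcium, HCN and TRP channel, inhibitory receptor, immediate-early, interferon, cytokine, antigen presentation, sterol, cell cycle, non-peptidergic and neutrophil lists (0.125 to 0.986). In CKO it ended 18, those of the same lists without the sterol list (0.108 to 0.915) and of the respiratory chain, neurotrophin, C low-threshold, satellite glial, lymphocyte and endothelial lists (0.0956 to 0.915). Non-peptidergic medians turned negative with it, and neutrophil medians positive. The replicate block ended the endothelial call in CKO (0.0560). Over all list and setting pairs, 760 kept their call, 135 lost it and 16 turned the direction of the test without a call.

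Genes shared by the 2 PTX responses numbered 527 at an adjusted p of 0.1 and 16 at 0.01. The share of opposite sign was 95.0 percent for the 500 smallest p. It was 34.5 and 85.7 percent with the PTX fl/fl libraries split, which also parts their dates. Ltbr under vehicle was -0.503 on the later title date and -0.078 by limma-voom. Scn10a under vehicle was 0.299 with the date block, 1.00 on the earlier title date, 0.0975 and 0.576 with the neutrophil and neuron covariates and 0.159 by limma-voom. With the glial and Schwann covariate, Ntrk2 (0.017) and Ednrb (0.288) in fl/fl and Ednrb in CKO (0.0738) turned sign. With that covariate, 100 of the 704 genes called in fl/fl and 3 of the 366 called in CKO had the other sign. Over all named genes and settings, 1927 kept their side of the threshold, 932 lost a call, 9 gained one, 19 moved and 3 turned sign from a call. Of the 64 and 47 named genes called for PTX in fl/fl and CKO, limma-voom and DESeq2 lost 0, with 63 of the 64 given a value by DESeq2. The quality weights of limma-voom favoured the earlier PTX date.

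Leaving out 1 library gave 177 to 845 genes for PTX in fl/fl, 30 to 549 in CKO, 0 to 0 for genotype under PTX, 1 to 15 under vehicle and 0 to 4 for the interaction. Lists ranged from 26 to 28, 24 to 28, 3 to 13, 0 to 9 and 1 to 7 in the same order. The highest gene counts were without replicate 4 of PTX fl/fl (845), replicate 3 of PTX CKO (549) and replicate 4 of vehicle CKO (15 and 4). Ltbr ranged from 0.61 to 1.16 under PTX and -0.243 to 0.397 under vehicle, and Scn10a from -0.74 to -0.0389 and -0.416 to 0.310.

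The depth and the spread between libraries limit what was called, since the simulated 2-fold changes were recovered for 0 percent of genes.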

Other observations

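The contrast of the 2 title dates within PTX, and the genes named for it, were chosen after their values were seen, and so were its tests.

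Within the PTX libraries, the 4 of the earlier date had lower neutrophil and macrophage markers than the 4 of the later date. S100a8 and S100a9, the calprotectin subunits of neutrophils, were each 5.16 lower on the log2 scale (-5.16 ± 0.48 and -5.16 ± 0.43, edgeR adjusted p = 8.7e-06 and 3.7e-06, n = 4 per date), the granule genes Ngp and Camp changed by -5.56 ± 0.43 and -5.25 ± 0.50, and Lyz2, the lysozyme of myeloid cells, by -4.79 ± 0.36. All 15 neutrophil markers were called lower, as were 16 of 23 macrophage markers and 9 of 24 cell cycle genes, Mki67 among them (-5.47 ± 0.98). Fos and Dusp1, immediate-early genes, fell by 2.01 ± 0.23 and 2.46 ± 0.21, and of their list 16 of 30 were lower and 2 higher. Of the lymphotoxin-beta receptor and NF-kB list 12 of 25 were lower (median -1.80), whereas Ltbr was at -0.82 ± 0.46 (edgeR adjusted p = 0.36).

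No list test was run for this contrast. On the earlier date 6 of 16 pan-neuronal markers were higher (median 0.96), as were 13 of 49 microtubule genes with 1 lower. Of the markers of neuron classes, 1 of 17 non-peptidergic ones was higher (median 2.21), none of 14 peptidergic ones was called (median 0.38), 1 was higher and 1 lower of 14 pruriceptor ones (median 0.59), 1 of 24 of myelinated mechanoreceptors was lower (median 0.73), and none of 11 of C low-threshold mechanoreceptors was called (median -0.51). Calca was at 0.79 ± 0.25 (edgeR adjusted p = 0.081). Satellite glial markers had a median of -0.25 with none called, and Schwann cell markers one of -0.44 with 2 of 20 lower. In all 1268 genes were called between these dates, 255 higher and 1013 lower on the earlier one, against 23 between the 2 vehicle dates, all lower on the earlier. No cause was tested.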
